A study of Mus musculus with 2 samples.

How the data were processed

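Single-cell RNA was measured in 2 libraries of YFP+ mouse thymus cells, 1 from Tbx21Cre Rosa26-YFP mice (control) and 1 from such mice with floxed Ets1 (cKO), each pooled from 2 mice per the labels. The deposited count matrices hold whole-number UMI counts for 32285 features, and per the labels they were made from 3' libraries with Cell Ranger 2.1.1 on the mm10 genome. The matrix headers name software version 3.0.0 instead, and this difference was not resolved. The aligner's settings and the gene annotation are not given in the sources used here. Every barcode in the deposited matrices held at least 500 UMIs.

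Cells with at least 500 genes and at most 10% of UMIs on mitochondrial genes were kept. Scrublet, run per library in scanpy, called 0 control and 10 cKO barcodes doublets, too few for the calling to have worked, so doublets are largely unremoved. Counts were summed over cells per gene and divided by the summed UMIs of all genes to give CPM. The ratio of CPM, cKO over control, has an exact conditional binomial 95% interval, with 0.5 UMIs added to both sums for the ratio itself. Levels have exact Poisson intervals and shares exact Clopper-Pearson intervals, and a count of 0 was set against a floor of 3 counts. With 1 library per group no test was made and no p is given. A gene met the size rule when its ratio was at least 1.5 in either direction, it reached 20 CPM in the higher library, and the interval of the ratio excluded 1.

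Ets1, Tbx21, Zbtb16, Cd8a, Cd8b1, Eomes, Il2rb and Cd4 were named whatever their values. Also named were the 8 genes with the highest and the 8 with the lowest ratio among those past the size rule that reach 50 CPM, leaving out mitochondrial, ribosomal protein, receptor segment, sex-linked and uncharacterised genes. From each of the gene lists, up to 4 members with the largest ratios were named, and a marker of each cell class where its share is given. Some genes that this rule names are not reported here. The filters, size rule, named genes and lists were fixed before the data were examined. The list of gut epithelium genes was written after the data were seen. Genes that lead clusters, the T cell receptor segments, the globin genes as a pair, and the neighbours of Fxyd7 were singled out after their values were seen. A list's median log2 ratio, over members reaching 10 CPM, was placed among 10000 random lists matched in 20 expression bins, as a description of these libraries.

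Both libraries were clustered together without integration: 10000 UMIs per cell after scaling, 2000 variable genes without receptor segments, sex-linked, mitochondrial and ribosomal protein genes, 30 components, 15 neighbours and Leiden resolution 0.8. A class planned for iNKT1 cells was not used, because cluster 4 had more leading markers of another class than of its own. In its place, clusters were taken in which Trav11 made at least 15% of Trav UMIs and reached 5 CPM. This rule was set after the cluster values were seen. The first rule tried, at least 10% of at least 20 Trav UMIs, also took in clusters 9 and 10. Cluster 9, named erythroid-like, had 14.4% Trav11, 312 control cells (4.22%) and 76 cKO cells (1.29%). Its top 10 genes held globin genes but also the cycling cell markers Hist1h1b, Rrm2 and Pclaf. A Trav UMI was held by 29 of its control and 24 of its cKO cells, so cycling T cells may have been left out with it. In the B-like cluster 10, 6 of 26 Trav UMIs were Trav11. Annotated near-copies of Trav11 make its counts uncertain. Shares of cells with a UMI were taken after thinning each cell to 1500 UMIs. Coordinates come from GENCODE vM21 on GRCm38, in which 99.6% of the feature identifiers were found.

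The size rule and the list percentiles were tested on simulated data with known folds. Counts there varied by counting error alone around 1 shared profile, without differences between cells, mice or libraries. The results are therefore not error rates for the comparison of these libraries. Of 67 genes with a 2-fold difference 66 met it, of 66 genes with a 3-fold difference 66, of 67 with a 1.3-fold difference 0, and of 32085 unchanged genes 0. Of 300 unchanged random lists, 7 fell below percentile 2.5 and 2 above 97.5. An earlier single unchanged list had fallen in the lowest tail, after which the check was widened to these lists. Alternatives covered the filters, doublets, scaling, thinning, thresholds, clustering and the population, and their effects are given in the closing section. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, umap-learn 0.5.12 and matplotlib 3.10.9.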

Results

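The data were single-cell RNA counts from mouse thymus. YFP+ cells were sorted from mice in which the Cre recombinase is driven by Tbx21, the gene of the transcription factor T-bet, and switches on a YFP reporter, so that YFP marks cells that have expressed T-bet. Such cells include the T-bet+ subset of invariant natural killer T cells (iNKT1 cells), T cells with a semi-invariant receptor built on the Trav11 segment. The control library carried intact Ets1 and the cKO library carried floxed Ets1, which encodes an ETS family transcription factor. There was 1 library per genotype, each pooled from 2 mice that cannot be told apart, so there is no replicate check and no test. All intervals are exact 95% intervals that cover counting error only. The control library held 10102 barcodes and 35210431 UMIs, and the cKO library held 11206 barcodes and 39979742 UMIs. After filtering, 7395 control cells with a median of 2666 UMIs and 5894 cKO cells with a median of 5532 UMIs remained. The filter on mitochondrial UMIs alone touched 6.76% of control and 28.6% of cKO barcodes.

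The targeted gene was lower in the cKO library. Ets1 (ENSMUSG00000032035, chromosome 9, 32636221 to 32757820 on the plus strand of GRCm38) stood at 493 CPM (its summed UMIs scaled to a common total of UMIs; interval 485 to 500) in control cells and at 151 CPM (147 to 155) in cKO cells, 3.26-fold lower (3.16 to 3.36). The library reads 3' ends and the labels do not say which exons are floxed, so this level may not measure the deletion itself. In NK-like cells Ets1 was 2.65-fold lower (2.29 to 3.07). In B-like cells of at least 3000 UMIs, where T cell markers were lower in cKO (median log2 ratio -1.06), Ets1 stood at 220 and 109 CPM. In DP thymocyte-like cells of that depth it was not lower, at 591 CPM in 15 control cells and 949 CPM in 37 cKO cells.

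The cells fell into 16 clusters, and few held both libraries in similar shares. Most control cells lay in cluster 0, led by the interferon-induced genes Ifit1 and Ifit3, cluster 1, led by the NK receptor genes Klra9, Klra3 and Klrb1c, and cluster 3, led by Izumo1r and Podnl1, with Zbtb16 among its top 10 genes. These held 17.9%, 26.8% and 25.4% of control cells and 1.54%, 1.80% and 1.58% of cKO cells. Most cKO lymphoid cells lay in cluster 4, with Klra5 and Lgals3 among its leading genes, and in cluster 6, led by Fxyd7, Fxyd1 and Calca, which held 15.8% and 18.5% of cKO cells against 1.60% and 0% of control cells. With 1 library per genotype, a cluster held mostly by 1 library may be that library and not a cell type. B-like cells, marked by Cd79a, made up 5.21% of control cells (4.71 to 5.74) and 6.68% of cKO cells (6.06 to 7.35), or 10.2% of the cKO cells left without clusters 12 to 15. DP thymocyte-like cells, marked by Rag1, made up 92 control and 55 cKO cells, 1.24% and 0.933%, or 1.43% of the cKO cells left without those clusters. Of all cells, the B-like share was lower in cKO at resolution 1.2 (5.60% and 5.21%), with doublet calls kept (5.41% and 5.25%) and without the highest doublet scores (4.78% and 4.31%). Without the gut-led and stromal-like cells in the total, it was higher in cKO in these settings too, with cKO shares of 7.98%, 8.05% and 6.53%. The size of the gap was not stable, as the shares on this total were 1.10% and 9.12% when differing genes were left out of the clustering and 2.34% and 7.64% in cells of at least 3000 UMIs. The DP share without them was lower in cKO at resolution 1.2, at 3.57% and 1.87%, so no direction is read for it. The B-like cells of the libraries also differed in content, as 7 of 9 myeloid or dendritic cell markers were higher in those of the cKO library (median log2 ratio 5.05) and 8 of 10 T cell markers lower (-2.01). In those of at least 3000 UMIs the medians were 2.52, with 4 of 8 higher, and -1.06, with 6 of 10 lower. NK-like cells, marked by Ncr1, made up 7.37% (6.78 to 7.99) and 3.17% (2.74 to 3.65), or 4.86% of the cKO cells left without clusters 12 to 15. When genes differing between the libraries were left out of the clustering, the shares were 3.14% and 2.04%, or 3.14% and 3.12% without the gut-led and stromal-like cells, so no difference in NK-like cells is read.

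**Figure D1:**
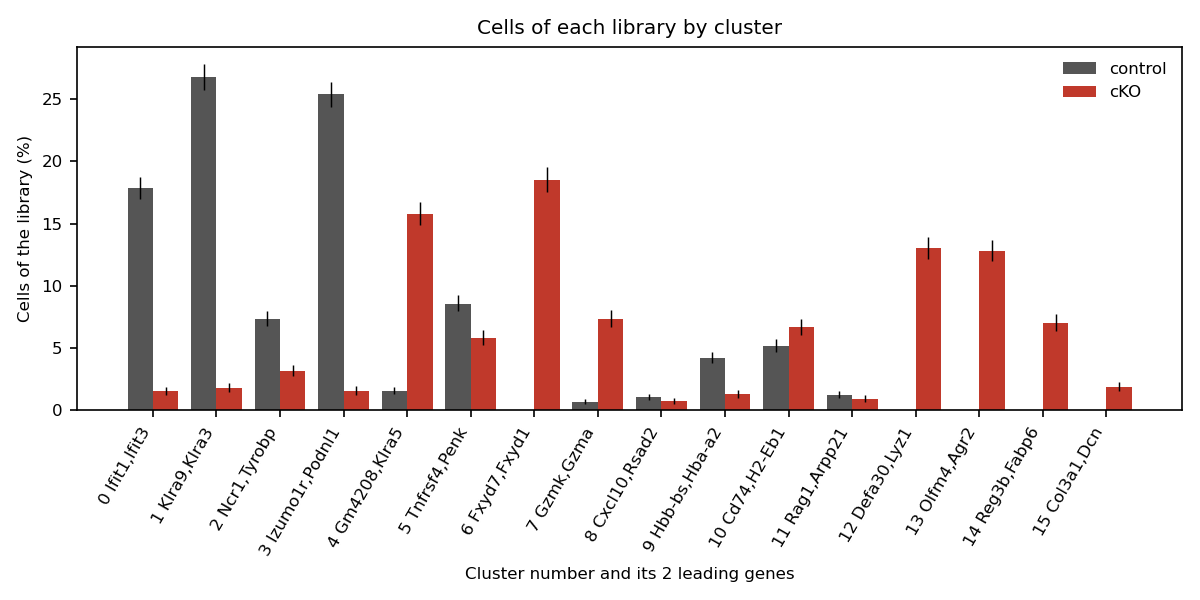
Percent of each library's cells in each of the 16 clusters, for the control and the cKO library, with exact binomial 95% intervals as error bars. Clusters 0, 1 and 3 hold mostly control cells, clusters 4, 6 and 7 mostly cKO cells, and clusters 12 to 15 cKO cells alone.

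Across all cells, the comparison of genotypes was led by genes of the intestinal epithelium. The genes with the highest cKO-to-control ratios were Zg16, a goblet cell lectin gene, at 2680 CPM in cKO cells, Fabp6, the ileal bile acid binding protein gene, at 2241 CPM, the defensin genes Defa24 at 1150 CPM and Defa30 at 741 CPM, Agr2 at 1016 CPM, Mptx1 at 472 CPM, Itln1 at 268 CPM, and the collagen gene Col3a1 at 128 CPM. Control cells held at most 16 UMIs of any of them. Clusters 12, 13 and 14, led by such genes and left unnamed, held 1939 cKO cells, 32.9% of the library (31.7 to 34.1), and 0 of 7395 control cells, which allows a share of up to 0.0406%. Together with the stromal-like cluster 15, led by Col3a1 and Dcn, they carried 13.2% of the cKO UMIs kept. By the size rule, 1006 genes were at least 1.5-fold higher and 329 at least 1.5-fold lower in cKO cells, and 289 of the former stood at least 5 times higher in these clusters than in other cKO cells. Without these clusters the numbers were 733 and 281. The median log2 ratio of genes at 20 CPM or more was 0.16. The split between higher and lower genes depended on scaling: higher genes made up 75.4% of the total, 63.1% with median-ratio scaling and 55.0% when the total left out mitochondrial and ribosomal protein genes.

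The genes lowest in the cKO library relative to control across all cells included single NK receptor genes and globin genes. Of 26 NK receptor genes 8 were higher and 9 lower (median log2 ratio -0.31, percentile 0), and of 10 T cell markers 0 were past the size rule. Klrb1c, which encodes NK1.1, stood at 155 CPM in control and 19.5 CPM in cKO cells, 7.94-fold lower (7.33 to 8.62). Klra3 was 10.7-fold lower (9.44 to 12.3), Klra9 4.96-fold lower (4.73 to 5.21), Podnl1 9.67-fold lower (8.38 to 11.3), Izumo1r 4.42-fold lower (4.14 to 4.72), and Gmfg 4.22-fold lower (4.04 to 4.41). The globin genes Hbb-bs and Hba-a1 stood at 144 and 55.1 CPM in control cells against 4.37 and 2.56 CPM. They led the erythroid-like cluster 9, which also held cycling cell markers among its top 10 genes. Without non-T-lineage and cycling clusters both were higher in cKO cells, with log2 ratios of 3.84 and 3.73. Tbx21 stood at 81.8 CPM in control cells and 96.6 CPM in cKO cells (ratio 1.18, 1.12 to 1.24), which did not reach the size rule. Weighting every cell equally gave a log2 ratio of 0.00 for Tbx21, so no direction is drawn for all cells. Zbtb16 stood at 40.8 and 32.1 CPM, Il2rb at 476 and 404 CPM, Cd4 at 29.3 and 25.9 CPM, and Eomes at 30.2 and 35.5 CPM.

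Cd8a and Cd8b1 were higher across all cKO cells, and most Cd8a UMIs lay in a cluster with almost no Trav11 UMIs. Of 25 genes of CD8 effector and memory T cells, 7 were higher and 2 lower (median log2 ratio 0.33, percentile 98.1). Cd8a stood at 67.0 CPM in control and 174 CPM in cKO cells (ratio 2.60, 2.48 to 2.73), and Cd8b1 at 121 and 243 CPM (ratio 2.00, 1.93 to 2.08). Of 5989 Cd8a UMIs in cKO cells, 4640 fell in cluster 7, led by Gzmk, Gzma, Ccl5, Cd8a and Cd8b1, which held 433 cKO and 51 control cells. The size of this cluster is not compared, since its leading genes differ between the libraries and clustering without such genes did not give it. In its cKO cells, 1 of 324 Trav UMIs came from Trav11 and 108 from Trav4-4-dv10, the latter spread over 28 of the 156 cells with a Trav UMI. Of cells thinned to 1500 UMIs, 6.48% of control (5.83 to 7.18) and 9.22% of cKO cells (8.40 to 10.1) held a Cd8a UMI, against 9.67% and 10.1% unthinned. For Cd8b1 the thinned shares were 9.86% (9.07 to 10.7) and 10.1% (9.25 to 11.02), and the unthinned shares 12.4% and 10.7%, so no order is read. In B-like cells, which should lack both genes, the thinned share was 4.29% in control and 0.606% in cKO for Cd8a and 5.58% and 1.82% for Cd8b1, at median depths of 2562 and 9002 UMIs before thinning. The thinned share for Klrb1c was 19.4% (18.3 to 20.5) and 2.41% (1.99 to 2.90), against 35.8% and 6.80% unthinned, and 8.58% and 0% of B-like cells, the latter allowing up to 0.909%. For Eomes it was 3.27% (2.80 to 3.79) and 3.48% (2.97 to 4.05), so no difference was detectable at this depth. Unthinned it was 5.98% and 7.97%, and in thinned B-like cells 0%, which allows up to 1.29%, and 0.909%. Thinning left out 2194 control and 1294 cKO cells.

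To compare genotypes in clusters likely to hold iNKT cells, clusters were pooled in which Trav11 made up at least 15% of Trav UMIs and reached 5 CPM. These were clusters 0, 1, 3, 4, 6 and 8, with 5375 control cells, mostly in clusters 0, 1 and 3, and 2356 cKO cells, mostly in clusters 4 and 6. This population was defined after the data had been examined. Trav11 made up from 20.6% (cluster 8) to 33.5% (cluster 6) of the Trav UMIs in these clusters, so most came from other segments. A Trav11 UMI was held by 3.09% of control and 5.86% of cKO cells there, unthinned, at median depths of 2932 and 6822 UMIs. Few cells held any Trav UMI. Of those that did and had no Cd8b1 UMI, 154 of 458 control (33.6%) and 133 of 363 cKO cells (36.6%) held Trav11. The pool is thus not shown to consist of iNKT cells alone. In it, Ets1 stood at 530 CPM in control (521 to 540) and 165 CPM in cKO cells (159 to 171), 3.22-fold lower (3.09 to 3.36). Tbx21 (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331 on the minus strand) stood at 89.3 CPM (85.5 to 93.2) and 156 CPM (150 to 162), 1.74-fold higher in cKO (1.64 to 1.85). With the cluster rule tried first the log2 ratio of Tbx21 was 0.58, which falls short of the size rule. By the size rule, 849 genes were higher and 354 lower in the cKO cells. Higher genes made up 70.6% of these, 50.2% with median-ratio scaling and 44.3% when the total left out mitochondrial and ribosomal protein genes. The median log2 ratio of genes at 20 CPM or more was 0.18, and gene lists are therefore set against matched random lists, whose medians lay near that value.

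The genes highest in cKO relative to control in these clusters included a group of neighbours on chromosome 7. Fxyd7, which encodes a regulator of the sodium pump (chromosome 7, 31042513 to 31051467), had 2 UMIs in control and 23977 in cKO cells (1417 CPM). Fxyd1 had 1 and 9370 UMIs, Lgi4 1 and 1204, and Fxyd3 2 and 880. Calca, which encodes calcitonin and CGRP, stood at 8.68 and 802 CPM (ratio 92.2, 80.6 to 107). The integrin genes Itgad and Itgax stood at 0.168 and 62.8 CPM and at 0.671 and 68.8 CPM, and the sphingosine phosphate receptor gene S1pr5 at 1.34 and 62.9 CPM (ratio 46.2, 33.0 to 69.0). Fxyd7 also stood at 69.2 CPM in cKO B-like cells of at least 3000 UMIs, and free RNA and doublets were not told apart there. Lowest relative to control were Rasgrp2, a Rap exchange factor gene, at 61.4 CPM (58.3 to 64.6) in control and 5.55 CPM (4.49 to 6.80) in cKO cells, Gmfg, an actin regulator gene, 10.5-fold lower (9.56 to 11.5), Klra3, 9.39-fold lower (8.04 to 11.1), Podnl1, at 70.3 CPM (67.0 to 73.7) and 7.68 CPM (6.42 to 9.12), Klrb1c, 9.04-fold lower (8.10 to 10.2), Traf1, 7.60-fold lower (6.30 to 9.30), Gpr132, 6.24-fold lower (5.29 to 7.45), and Atp8a2, 5.54-fold lower (4.77 to 6.48).

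**Figure D2:**
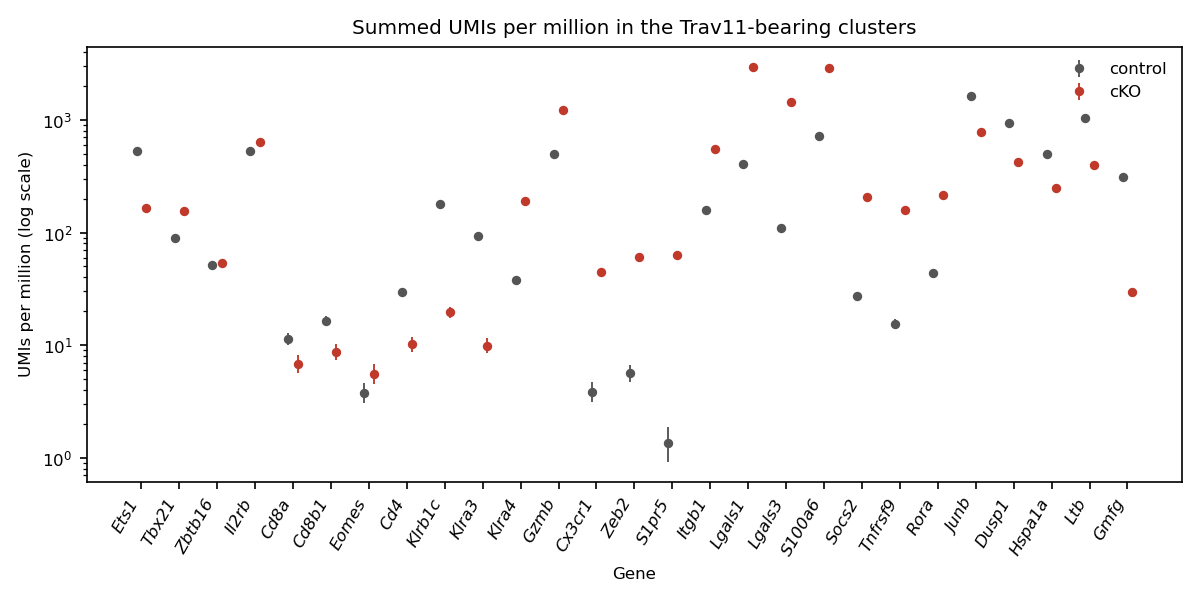
CPM of summed UMIs on a log scale for selected named genes in the Trav11-bearing clusters of the control library (5375 cells) and the cKO library (2356 cells), with exact Poisson 95% intervals as error bars. Ets1, Klrb1c and Gmfg lie lower, and Lgals3, S100a6 and S1pr5 higher, in the cKO library.

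The medians of effector gene lists stood higher in cKO Trav11-bearing clusters, though not all members did. The libraries filled these clusters unequally, as the iNKT2-like cluster 3 held 1878 of the 5375 control and 93 of the 2356 cKO cells. Over the pool, however, iNKT2 markers were not lower as a group, with 2 higher and 1 lower of 10 (median log2 ratio 0.26, percentile 68.4). For iNKT1 markers it was 7 and 4 of 20 (0.19, 70.2). A lower iNKT2 content of the cKO cells is thus not shown. Markers of 4 other cell types went both ways within their lists, while their medians lay in the tails of the random lists. Of 8 NK cell markers 2 were higher and 2 lower (median -0.44, percentile 0.13). Of 8 mature CD8 T cell markers it was 2 and 2 (-0.59, 0.01), and of 7 CD8aa IEL precursor markers 1 and 2 (-0.46, 0.37). Of 5 regulatory or CD4 T cell markers it was 2 and 1 (0.67, 98.0). In cells of at least 3000 UMIs the percentiles were 0.26, 2.75, 11.9 and 97.3, in that order. Only the NK cell list stayed in a tail there, so no direction is read for the others. Of 7 gut epithelium genes 2 were higher and 0 lower (median 4.58, percentile 100), and of 3 myeloid or dendritic cell markers 2 and 0 (1.28, 99.8). Unthinned, 54.6% of cKO and 2.01% of control cells here held a UMI of the gut epithelium list, at median depths of 6822 and 2932 UMIs. Of 17 measured cytotoxic effector genes, 7 were higher and 2 lower (median log2 ratio 0.37, percentile 98.2 among 10000 matched random lists). Gzmb stood at 494 and 1226 CPM (ratio 2.48, 2.43 to 2.54). Gzma was lower, at 280 and 106 CPM, but its direction turned in 4 alternative groupings of the cells, given in the closing section. Of 21 genes of CD8 effector and memory T cells, 7 were higher and 0 lower (median 0.36, percentile 97.9). Among them, the fractalkine receptor gene Cx3cr1 stood at 3.86 and 44.9 CPM (ratio 11.6, 9.37 to 14.6), the transcription factor gene Zeb2 at 5.62 (4.71 to 6.65) and 60.7 CPM (57.1 to 64.6), and Itgb1 at 158 and 555 CPM (ratio 3.52, 3.39 to 3.66). Cd8a stood at 11.4 and 6.80 CPM, Cd8b1 at 16.4 and 8.75 CPM, and Eomes at 3.77 and 5.56 CPM. Of 22 NK receptor genes, 10 were higher and 4 lower (median 0.13, percentile 34.7), and the members moved apart: Klra4 stood at 38.2 (35.7 to 40.7) and 189 CPM (183 to 196) and Klrb1a at 5.49 and 27.3 CPM, whereas Klrb1c and Klra3 were lower. The T-bet programme list had 7 genes higher and 4 lower of 21 (median 0.28, percentile 92.1), with Txk at 264 and 520 CPM and Ccl4 at 30.9 and 4.20 CPM.

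Genes of the cytoskeleton, S100 proteins and galectins were higher as a group. Of 21 measured, 13 were higher and 0 lower (median log2 ratio 0.84, percentile 100). Lgals3 stood at 110 and 1453 CPM (ratio 13.2, 12.7 to 13.8), Lgals1 at 403 and 2940 CPM (ratio 7.30, 7.14 to 7.46), S100a6 at 720 and 2899 CPM (ratio 4.03, 3.96 to 4.10) and Anxa1 at 35.2 and 143 CPM. Migration genes had 7 higher and 5 lower of 22 (median 0.44, percentile 99.8), with S1pr1 at 11.8 and 41.1 CPM, and with the oxysterol receptor gene Gpr183 lower, 3.49-fold (3.16 to 3.86). Genes of oxidative phosphorylation had 4 higher and 0 lower of 30 (median 0.34, percentile 99.1), such as Ndufa1 at 164 and 322 CPM. The signalling inhibitor gene Socs2 stood at 27.2 (25.2 to 29.4) and 207 CPM (201 to 214), Ifngr1 at 384 and 1042 CPM, the costimulatory receptor gene Tnfrsf9 at 15.4 and 157 CPM, and the transcription factor gene Rora at 43.5 and 214 CPM (ratio 4.92, 4.59 to 5.28).

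Genes induced by T cell receptor signalling, immediate early genes among them, were lower as a group. Of 23 measured, 15 were lower and 0 higher (median log2 ratio -0.85, percentile 0). Junb stood at 1615 and 774 CPM, Dusp1 at 931 and 427 CPM, and Egr3 at 21.0 and 6.56 CPM. Dissociation and heat shock genes had 5 lower and 0 higher of 13 (median -0.39, percentile 0.17), with Hspa1a at 496 and 248 CPM. Glycolysis genes had 4 lower of 14 (median -0.22, percentile 0.050), with the glucose transporter gene Slc2a3 at 40.9 and 14.5 CPM. Interferon-stimulated genes had 5 lower and 1 higher of 28 (median -0.17, percentile 0), with Rtp4 at 80.6 and 44.0 CPM. The interferon-led clusters 0 and 8 held 1399 of the control and 134 of the cKO cells, and interferon-response cell markers had a median of -0.42. Cytokine genes had 4 lower and 2 higher of 10 (median -0.22, percentile 1.2), with Ltb at 1032 and 400 CPM (2.58-fold lower, 2.51 to 2.65) and Il4 higher, at 44.3 and 84.3 CPM. Among lineage transcription factors 6 were higher and 5 lower of 34 (median 0.29, percentile 93.6), with Hivep3 at 28.6 and 4.49 CPM and Id3 at 28.4 and 5.85 CPM, while Zbtb16, which encodes the iNKT factor PLZF, stood at 51.9 and 54.0 CPM. T cell receptor signalling components had 6 higher and 0 lower of 29 (median -0.01, percentile 3.65), with Sh2d1a and Themis among the higher genes. The Gimap family of GTPase genes had a median of -0.20 (percentile 3.47) and S phase genes one of -0.03 (percentile 1.98), but the S phase median was above 0 under 7 alternatives (0.056 to 0.31), so no direction is read for it. The lists of ETS family genes (median 0.29, percentile 78.3), cytokine receptors and survival (0.14, 40.7), inhibitory and activation receptors (0.13, 35.2), G2/M phase (0.14, 43.5) and MHC class I (0.17, 55.5) lay well inside the range of the random lists.

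**Figure D3:**
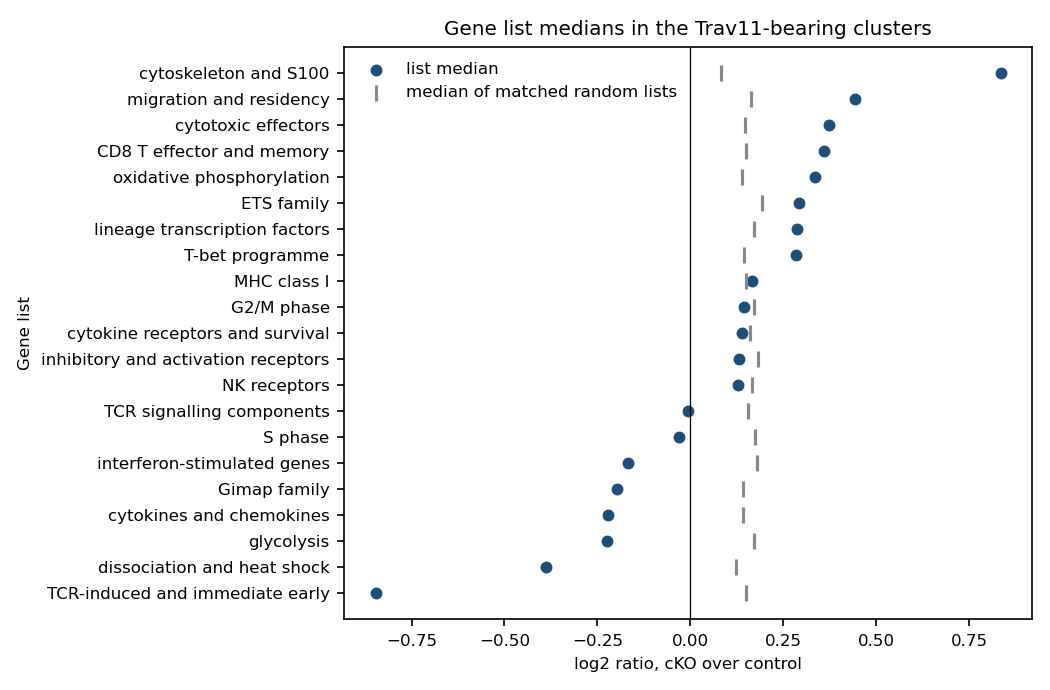
Median log2 ratio, cKO over control, in the Trav11-bearing clusters, of each gene list fixed before the data were examined and plotted here (points) and the median over matched random lists (ticks). Of the lists plotted, the cytoskeleton and S100 list lies highest, at 0.84, and the list of receptor-induced and immediate early genes lowest, at -0.85.

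In NK-like cells, which also express T-bet, some differences had the direction seen in the Trav11-bearing clusters and others did not. There were 545 control cells with a median of 1853 UMIs and 187 cKO cells with a median of 8292 UMIs. The cell content of the cluster differed too, as 6 of 7 gamma-delta T cell markers (median log2 ratio 0.97) and 4 of 5 iNKT17 markers (2.21) were higher in cKO. Gzmb stood at 387 and 1037 CPM (ratio 2.68, 2.46 to 2.93), Cx3cr1 at 36.4 and 137 CPM (119 to 157), Cd160 at 149 and 344 CPM and Lgals1 at 1249 and 3411 CPM (ratio 2.73, 2.60 to 2.87). Gzmc had 525 UMIs in control and 1 in cKO cells (262-fold lower, 70.2 to 15537). Klrb1c stood at 312 and 211 CPM, a smaller gap than in the Trav11-bearing clusters, and Tbx21 at 119 and 160 CPM. The difference between the classes was not tested. Of 18 cytotoxic effector genes, 5 were higher and 2 lower (median log2 ratio 0.41, percentile 100), and of 25 receptor-induced and immediate early genes 1 was higher and 11 lower (median -0.40, percentile 0), with a median of -0.72 in cells of at least 3000 UMIs. Migration genes (median -0.22, percentile 0.12) and MHC class I genes (-0.27, percentile 0.17) lay low in NK-like cells, unlike in the Trav11-bearing clusters. Interferon-stimulated genes lay low in both, in NK-like cells with 12 lower and 1 higher of 25 (median -0.62, percentile 0).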

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

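The tests of gut UMIs in B-like cells were chosen after the result was seen, and that of thymic epithelial genes before. Genes of a list of 22 gut epithelium genes, outside the T cell measurement, made up 1.70% of UMIs kept in the cKO library (585450 UMIs) and 250 UMIs in the control library. Cells led by such genes were 32.9% of cKO cells. In them Fabp6 reached 17656 CPM, Zg16 21261 CPM, Defa24 9100 CPM and Reg3b 4733 CPM, while Cd3e stood at 5.34 CPM and Tbx21 at 0.464 CPM. A sort for YFP+ cells would remove cells without a history of Tbx21 expression.

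Thymic epithelial cells can express gut genes, but 8 thymic epithelial genes summed to 3.48 CPM in these clusters, while 6 posterior genes, Cdx1 and Cdx2 among them, summed to 266 CPM against 1.13 CPM in other cKO cells, which argues against that origin. Reads of another library assigned to the cKO library were taken to sit in their own barcodes and to leave B-like cells as clear of gut RNA as in the control. Yet 30.6% of cKO B-like cells thinned to 1500 UMIs held a gut UMI, against 2.58% of control B-like cells, which goes against that expectation. Whether such reads could also fall on barcodes of B-like cells was not tested, so this explanation is not excluded. The B-like cells of the libraries differed in content and doublets were largely unremoved, which limits this test. Before thinning, 54.6% of cKO and 2.01% of control cells of the Trav11-bearing clusters also held a gut UMI, at median depths of 6822 and 2932 UMIs. Gut cells or their RNA in the cKO cell suspension may have been the source, and the 30.6% share is what this predicts. How they entered was not tested. Whether the genotype has a part in it was not tested.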

How the results depend on the processing

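Alternatives that left out gut-led clusters, set 3000 UMIs, removed the highest 8% of doublet scores, or regrouped the Trav11-bearing clusters by another clustering or rule were chosen after the data were seen. No paired analysis was possible because each group is 1 pooled library. The planned iNKT1-like class was not run, as it did not hold together, nor the split by sex, as Y-linked genes had 1 and 5 UMIs. Of comparisons of main results with alternatives, 84 stayed within their limits and 53 moved; of those of single genes, lists and shares, 1995 stayed, 1047 moved and 24 reversed. Unless stated, the cause was not tested.

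In all cells the log2 ratio of Ets1 was -1.70, and -1.61 with at most 5% mitochondrial UMIs, -1.81 with median-ratio scaling, -1.90 with the total without mitochondrial and ribosomal protein genes and -1.56 without gut-led and stromal-like clusters. That of Tbx21 was 0.24, and in the same order 0.34, 0.14, 0.040 and 0.44, -0.0025 with every cell weighted equally, 0.34 in thinned cells and 0.37 without non-T-lineage clusters. Numbers of higher and lower genes were 1716 and 520 with every cell weighted equally, and 738 lower with the reduced total. By construction they moved to 1667 higher at a 10 CPM minimum, 459 and 175 at 50 CPM, 5826 and 1063 with none, and 505 and 126 at 2-fold.

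In Trav11-bearing clusters Ets1 was -1.69, and -1.84 with median-ratio scaling, -1.56 with equal weights, -1.88 with the reduced total, -1.75 with the rule tried first and -1.75 at 3000 UMIs. Tbx21 was 0.80, and 0.65 with median-ratio scaling, 0.96 with equal weights, 0.61 with the reduced total, 0.99 in thinned cells, 0.70 with clustering without genes differing 1.5-fold and 0.58 with the rule tried first, short of the size rule. Numbers were 501 higher with median-ratio scaling, 718 lower with the reduced total, 465 and 172 at 50 CPM, 2413 and 1259 with no minimum, and 290 and 151 at 2-fold.

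Gzma, lower in these clusters, was higher with doublet calls kept (0.13), resolution 1.2 (0.26), clustering without differing genes (1.26) and the rule tried first (0.42). The S phase median of -0.03 turned to 0.19 at 200 genes per cell, 0.24 with doublet calls kept, 0.056 in thinned cells, 0.22 at resolution 1.2, 0.27 without differing genes, 0.31 with the rule tried first and 0.11 without the highest doublet scores.

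In all cells, leaving out non-T-lineage and cycling clusters, the erythroid-like one among them, turned Hba-a1 to 3.73 and Hbb-bs to 3.84, the cytokine list to 0.35 and the T-bet programme list to 0.20. The T-bet list was 0.023 at 5% mitochondrial UMIs and 0.10 without gut-led clusters, and the cytokine receptor list 0.012 and 0.065. Without gut-led clusters Atf3 was -1.56, Ifitm2 -1.07, Ifitm3 -0.34 and the T cell receptor signalling list 0.072. Rrm2 was -0.19 with equal weights. The gut-led share was 31.6% with doublet calls kept, 46.7% at 200 genes per cell and 9.76% at 3000 UMIs. The NK-like share of control cells was 35.7% at resolution 0.4, 3.14% without differing genes, 16.2% with doublet calls kept, 19.9% at 200 genes, 4.66% without the highest doublet scores and 5.31% at 3000 UMIs. In cKO it was 5.19%, 2.04%, 4.46% with doublet calls kept and 3.93% at 3000 UMIs.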

Other observations

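Of the tests in this part, those of the immediate early genes and of the Fxyd7 neighbourhood were chosen after the results were seen, and that of a shift of the whole library before. The receptor-induced and immediate early genes, called immediate early here, were lower in the cKO Trav11-bearing clusters, where Ets1 was also lower. If the lower Ets1 level were the whole cause, classes in which Ets1 was not lower would not show the pattern. The list median was -0.77 in DP thymocyte-like cells of at least 3000 UMIs, where Ets1 was higher in cKO, and -0.51 in the whole class. At that depth the class held 15 and 37 cells, and 12 of 19 iNKT1 markers were lower there too (median -2.05). Its control barcodes may thus carry more RNA of the T cells in which immediate early genes were high, so the value does not exclude the lower Ets1 level. The list lay below percentile 2.5 in 4 of the 4 other classes, as handling or another difference between whole libraries would give. These were cluster 5 and the NK-like, B-like and DP thymocyte-like cells of at least 3000 UMIs. In B-like cells of all depths the list lay at percentile 16.8. The dissociation and heat shock list, which bears on handling, lay at percentile 0.17 in the Trav11-bearing clusters, and at 0.775 in NK-like and 0 in DP thymocyte-like cells of at least 3000 UMIs, but at 7.55 in B-like cells of that depth and 5.04 in cluster 5. Cell content differed in these classes as well: iNKT1 markers were lower in cluster 5 (median -0.61) and in B-like cells of at least 3000 UMIs (-0.60). Regulatory or CD4 T cell markers were higher in cluster 5 (8 of 8), and gamma-delta T cell markers were higher in NK-like cells. In cluster 5, where Ets1 was less than 1.5-fold lower (384 and 278 CPM, ratio 0.723), 2 immediate early genes were lower and 5 higher. Their median of 0.01 lay below that of matched random lists, 0.25 (percentile 1.17), which the lower Ets1 level as the whole cause would not give. Because iNKT1 markers were lower in cluster 5 too, this value does not decide between the explanations. The lower Ets1 level and a difference between whole libraries cannot be told apart here for these genes.

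The separation of the libraries in the Trav11-bearing clusters may come from Ets1 or from a technical shift of the whole cKO library. The gap between the median log2 ratios of the higher and the lower genes was 1.71 in these clusters, and 1.72 in their cells of at least 3000 UMIs. The other classes were taken at that depth alone. In B-like cells (92 control and 273 cKO) the gap was 33.2% of 1.71. Ets1 was lower in these B-like cells too, at 220 and 109 CPM, so they are not a reference with unchanged Ets1. T cell markers were lower in them as well (6 of 10, median log2 ratio -1.06), so this Ets1 level is not shown to be that of B cells. At that depth the gap was 47.4% of 1.71 in DP thymocyte-like cells (15 and 37), 50.4% in cluster 5 (405 and 318) and 71.5% in NK-like cells (205 and 151). A shift as the whole cause was set in advance to give at least 66.7% in B-like and DP thymocyte-like cells, which neither reached. However, the genes were picked by their ratios in the Trav11-bearing clusters, which enlarges the gap there and not in the other classes. A shift of the whole library could thus also fall short of that limit, so missing it does not exclude a shift. A value under 33.3% in both, set in advance to exclude it, was narrowly met in B-like cells alone. For a shift as part of the cause, library and genotype cannot be told apart, as they are the same split.

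Fxyd7, Fxyd1, Fxyd3 and Lgi4 lie side by side on chromosome 7. Higher expression across 1 stretch of the chromosome may account for all of them, but of 4 other measured genes within 200 kb 25% was higher by the size rule. So few genes cannot decide it.

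Outside DP thymocyte-like cells, 13 of 111 control cells with a Cd8b1 UMI and a Trav UMI held Trav11 (11.7%, 6.39 to 19.2), and 9 of 194 cKO cells did (4.64%, 2.14 to 8.62). Of these cells, 10 control and 148 cKO cells lay in cluster 7, where 0 and 1 held Trav11. In the Trav11-bearing clusters it was 12 of 23 control (52.2%, 30.6 to 73.2) and 5 of 12 cKO cells (41.7%, 15.2 to 72.3). No difference between the genotypes is therefore read. In cluster 5, Cd8b1 stood at 631 CPM in control and 101 CPM in cKO cells, Cd4 at 37.3 and 195 CPM, and Ctla4 at 37.0 and 205 CPM.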
